A study of Mus musculus with 4 samples.

How the data were processed

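Total RNA of 4 mouse peritoneal macrophage samples was measured, 1 array per group: wild type untreated, wild type with IL-4, Dap12-KO untreated and Dap12-KO with IL-4, each after 18 hours of culture. Per the labels' protocols, biotin-labelled cRNA was made with 2 cycles of amplification and hybridised to 1-colour Affymetrix arrays. The deposited values are log2 probe set values made with RMA, per the submitters' processing notes, which give no version. RMA usually includes quantile normalization of probe intensities before they are summarized, which leaves probe set distributions close but not identical. One deposited column was narrower than the others, and the sources used here do not say why. Amplification and normalization both act on the size of differences, and 2 amplification cycles favour the 3' part of transcripts.

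The table held 45101 probe sets. Gene names came from GEO's platform annotation, with symbols updated through Entrez identifiers to the RefSeq gene table of GRCm38.p6, where 34741 probe sets matched. Of all probe sets 34945 named 1 gene, 932 several and 9160 none, and 64 were controls. Probe sets with several genes or none entered no gene count. For the 18193 genes, the probe set with the highest mean over the 4 arrays was used, and 9010 genes had more than 1. A gene entered a comparison where its highest value on the 4 arrays reached the median of all values, 6.39, which left 12767 genes. Probe-level files were not used here, so no depth or detection call stands behind a value.

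Samples were grouped by their titles. The design, thresholds, 26 gene lists and the rule for named genes were fixed before the data were examined. For each of 5 comparisons (IL-4 in each genotype, genotype in each treatment and the difference of both IL-4 responses) log2 differences were computed and genes at 2-fold or more counted. Each gene list's median was set against 10000 random lists of the same size, matched on mean level in 20 bins, and a list is called high or low at or beyond percentiles 97.5 and 2.5, a description of these arrays with no p. The lists cover alternative activation, IL-4 receptor signalling, cell fusion, DAP12 receptors and ITAM signalling, inflammatory cytokines, interferon response, MHC class II, cell cycle, cholesterol synthesis, LXR targets, fatty acid oxidation, glycolysis and hypoxia, lysosome, integrins, matrix proteases, stress and immediate early genes, macrophage identity, resident cavity macrophages, markers of 7 other cell types and sex-linked genes.

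The IL-4 effect over both genotypes was tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with genotype as a block and Benjamini-Hochberg adjusted p-values. Genotype had no main test, since nothing in the labels says that both arrays of a genotype came from different mice. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The fit was tested on simulated data with 200 of 12767 genes changed by IL-4 in both genotypes. With equal spread for every gene it recovered 10% of changes of 1 log2 unit, 88% at 2 and 100% at 3, with 6 false calls among 155. With spread differing between genes these were 0%, 26% and 92%, with 7 false calls among 116. Neither simulation held a narrower array or a shift of the IL-4 response between genotypes. On the real arrays the median gene's response differed by −0.36, so these rates need not hold there. For the untreated genotype comparison, 5.5% of 200 random lists of 20 genes fell outside the central 95%, and 85% did after 0.3 was added to their genes.

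Named genes were Tyrobp; the 8 highest and 8 lowest genes of each comparison of 2 arrays, and of the mean IL-4 response among genes at 2-fold in the same direction in both genotypes; 6 and 6 for the difference of responses; up to 4 members of each list with the largest absolute difference; and genes that IL-4 moved 2-fold in opposite directions in the 2 genotypes. Mrc1, Ccl17 and Dcstamp in the plot of levels, Erdr1, S100a8 and Fbxo32 in the additional observations, and members of lists named there, were chosen after their values were seen. The alternatives tried were no level floor, a floor at the 75th percentile, a 3-fold threshold, cyclic loess (3 iterations), median centring, the median over probe sets, every probe set on its own, all list members, Spearman's rho, an intensity trend in eBayes and no genotype term. Lists of clock, FOXO and ERK pathway genes were drawn up after values had been seen, and all list members with cyclic loess was added then too. Quantile normalization was added after the narrower array had been seen.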

Results

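Gene expression was measured in mouse macrophages taken from the peritoneal cavity after thioglycolate, an irritant that draws macrophages into the cavity. The cells came from wild type mice and from mice labelled Dap12-KO, and were kept for 18 hours on slides untreated or with interleukin-4 (IL-4), a cytokine that drives alternative activation and fusion of macrophages. DAP12 is the adaptor protein encoded by Tyrobp, which passes signals from partner receptors through its ITAM motif. The study's stated purpose was to learn how loss of DAP12 changes macrophage expression at rest and after IL-4. Each of the 4 combinations was measured on 1 array, so there are no replicates and differences between 2 arrays are given as values with no test. The number of arrays limits the precision of every value below. All values are log2, and a gene was counted as higher or lower at 2-fold or more, among 12767 genes above a level floor of 6.39.

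The 4 arrays did not share one distribution of values. The middle 50% of values spanned 3.25, 3.24 and 3.19 log2 units on the wild type untreated, wild type IL-4 and untreated Dap12-KO arrays, and 2.54 on the array labelled Dap12-KO with IL-4. Bright probe sets read lower on that last array, with an upper quartile of 8.01 against 8.56 and 8.53 on the wild type arrays. Over all probe sets it correlated with the other arrays at r between 0.936 and 0.949, while both wild type arrays correlated at 0.991. The median gene differed by −0.40 between both Dap12-KO arrays and by −0.39 between both IL-4 arrays, against −0.03 for IL-4 in wild type and 0.03 between both untreated arrays. Comparisons that use the array labelled Dap12-KO with IL-4 are therefore set against level-matched random gene lists and, where the scaling mattered most, values after cyclic loess, which brings the arrays onto a common level trend. Of 96 values of named genes, 22 moved by over 1.5-fold with cyclic loess.

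**Figure D1:**
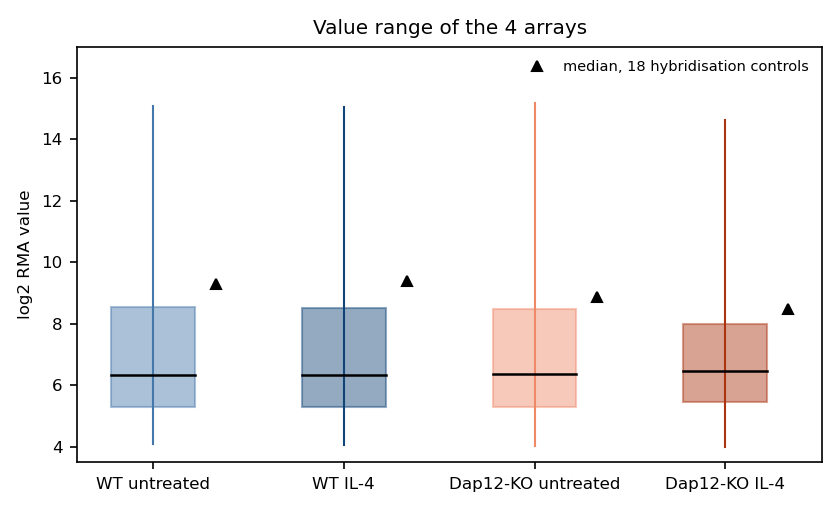
Value range of each array in log2 RMA units, with the 4 arrays on the x axis. Boxes span the quartiles, black lines mark medians, vertical lines run from the lowest to the highest value and triangles mark the median of 18 controls added at hybridisation, which was 9.30, 9.38, 8.89 and 8.47 from left to right. The box of the array labelled Dap12-KO with IL-4 is the narrowest, from 5.47 to 8.01.

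Tyrobp, the targeted gene, was bright on all 4 arrays. Its only probe set read 14.39 in wild type untreated, 14.13 in wild type with IL-4, 14.03 on the untreated array labelled Dap12-KO and 13.27 on the IL-4 array labelled Dap12-KO. These values lay above 99.8%, 99.7%, 99.6% and 99.4% of the probe sets of their array. The arrays labelled Dap12-KO were thus lower by no more than a log2 difference of −0.36 untreated and −0.86 with IL-4, or −0.29 and −0.45 after cyclic loess. The signal thus does not bear out the label. Where the probes lie relative to the deleted part of the gene is not known, and a probe set outside it would check nothing. Every direction drawn between genotypes below rests on the labels alone. Xist, which is read from the inactive X chromosome of females, was at 13.21, 13.21, 13.43 and 12.97 on the 4 arrays in the same order. The Y chromosome genes Eif2s3y, Kdm5d and Uty were below the level floor on all 4.

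In wild type macrophages, IL-4 was accompanied by higher levels of genes known from alternative activation and by lower levels of interferon-stimulated and cholesterol synthesis genes. Arginase 1 (Arg1) was 10.2-fold higher with IL-4, at 14.66 against 11.31. The log2 differences of the chitinase-like lectin Chil3, the C-type lectin Mgl2 and the chemokine Ccl22 were 2.38, 2.92 and 2.42. Ddx4, an RNA helicase known from germ cells, differed by 7.13, from 4.58 to 11.71. The untreated values of Ddx4, Rnase2a, S1pr3 and Tuba8 in wild type, and of Socs1 named below, lay below the level floor, so the sizes of these differences rest on background readings. Tmem26, the eosinophil-type ribonuclease Rnase2a, the sphingosine phosphate receptor S1pr3, endothelin 1 (Edn1), the creatine synthesis enzyme Gatm, Tuba8 and Plekhf1 were higher by 4.29, 4.29, 3.76, 3.72, 3.66, 3.62 and 3.57. At the other end, the formyl peptide receptor Fpr2 differed by −3.78, haptoglobin (Hp) by −2.68, Gpr84 by −2.42, Fabp7 by −2.37, Vsig8 by −2.28, the pattern receptor Clec4e by −2.13, Cd24a by −2.05 and Arap3 by −2.04.

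Of 12767 genes, 155 were higher and 160 lower in wild type with IL-4. Among the alternative activation genes 19 of 31 were higher, 0 lower and 12 neither, with a mean difference of 1.39 and a median that exceeded all 10000 level-matched random lists. Among the fusion and osteoclast genes, 4 of 24 were higher and 0 lower, namely the integrin chain Itgb3 (2.10), the adhesion molecule Cdh1 (2.05), the fusion protein Ocstamp (1.76) and the chemokine Ccl2 (1.15). The list's median of 0.14 exceeded all random lists. Cdh1 also stands in the alternative activation list and Ccl2 in the inflammatory list. Feedback inhibitors of cytokine signalling made up the 4 of 16 IL-4 receptor pathway genes that were higher, with Socs2 at 3.14, Cish at 2.82, Socs1 at 1.59 and Socs3 at 1.19, while the median of that list was −0.02 and its mean 0.37.

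Interferon-stimulated genes had a median of −0.78 in wild type with IL-4, with 11 of 27 lower and 0 higher; Oas3, Oas2 and Ifit1 differed by −1.84, −1.73 and −1.59. In the cholesterol synthesis list, 4 of 19 genes were lower, Sc5d (−1.24), Fdps (−1.22), Fdft1 (−1.19) and Cyp51 (−1.04), or 1 of 19 by the median over probe sets, and the list median was −0.70. The limma fit over both genotypes, given below, passed 0 of the 19, with 8 at an unadjusted p under 0.05. Both medians lay below all random lists. Of 25 genes for DAP12, its partner receptors and ITAM signalling, 4 were lower, among them the DAP12 partner receptor Clec5a (−1.67), Sirpb1a (−1.24) and the kinase Ptk2b (−1.13), and 0 were higher. That list's median of −0.26 and the glycolysis and hypoxia list's median of −0.27 were also below all random lists. The LXR target list (median −0.33, percentile 0.02) and the integrin list (−0.20, percentile 0.43) were low in the same way. At 2-fold, 0 of 23 glycolysis genes were lower and 1 higher, 0 of 14 LXR targets either way, and 2 of 21 integrin genes lower and 1 higher. On the arrays labelled Dap12-KO none of these lists but the interferon list was low for its level with IL-4. Cholesterol synthesis was at percentile 12.7, the DAP12 list at 27.0, glycolysis at 11.3 and integrins at 4.94. LXR targets lay within the central 95% as well. At 2-fold there, 7 of 19 cholesterol synthesis genes were lower and 1 higher, and 7 of 25 DAP12 list genes lower and 0 higher. Lower and higher were 6 and 0 of 23 glycolysis genes and 7 and 2 of 21 integrin genes. For LXR targets these were 3 and 0 of 14. The median of all genes was −0.40 there, so these counts do not show larger falls. The SD over all genes was 0.86 there against 0.37 in wild type, so the percentiles do not show that the falls were absent. In wild type with IL-4, immediate early and stress genes (0.08, percentile 99.3) were high for their level, with 0 of 29 higher and 1 lower at 2-fold. Dendritic cell markers (0.16, percentile 98.2), which share Ccl22 and Batf3 with the alternative activation list, were high above the floor only, at percentile 50.3 and a median of −0.03 with all 14 measured members. MHC class II genes (percentile 68.0), cell division genes (69.2), inflammatory cytokines (12.1), matrix proteases (96.8), fatty acid oxidation (16.6), lysosomal genes (2.60) and general macrophage genes (3.81) lay within the central 95%. Markers of neutrophils (50.5), eosinophils (62.7), B cells (45.2), T and NK cells (24.3), mast cells (13.6), mesothelium and fibroblasts (74.1) and resident cavity macrophages (87.6) did too.

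On the arrays labelled Dap12-KO, the alternative activation genes were again higher with IL-4. Chil3, Ccl22, Mgl2 and Arg1 differed by 3.09, 2.98, 2.61 and 1.93, and 21 of the 31 genes of the list were at least 2-fold higher and 0 lower. Tmem26 was 37.6-fold higher, and Rnase2a went from below the level floor to 10.98. The oxysterol enzyme Ch25h stood out with a difference of 4.35, against 0.33 in wild type, and Cdh1 went from 6.85 to 10.85, against 11.28 to 13.33 in wild type. Lower with IL-4 were Nxpe4 (−4.48), the transcription factor Fli1 (−3.70), the chemokine receptor Cxcr4 (−3.51), the condensin subunit Ncapg2 (−3.48), the clock output factor Dbp (−3.44) and thrombomodulin (Thbd, −3.39). Each of these genes kept its side of 2-fold after cyclic loess. Nxpe4, Fli1 and Thbd with IL-4 lay below the level floor, so the sizes of their differences rest on background readings. Ch25h untreated read 6.42, just above the floor, so its size is uncertain in the same way.

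As deposited, 1026 genes were higher and 2249 lower between both arrays labelled Dap12-KO. This split turned to 1238 higher and 755 lower after cyclic loess, to 1514 and 1109 after quantile normalization and to 766 and 2864 after median centring. The percentiles of the gene lists, already matched on level, were steadier than the counts or the list medians. Alternative activation had a median of 1.42 where random lists had −0.53, and 1.98 against −0.01 after cyclic loess, above all random lists in both. The fusion list (percentile 100, 4 higher and 2 lower of 24), inflammatory cytokines (percentile 100), stress and immediate early genes (99.98) and matrix proteases (99.7) were also high for their level. Of these, the medians of the fusion list (−0.20), the stress genes (−0.22) and the proteases (−0.08) were negative as deposited and positive after cyclic loess, at 0.33, 0.43 and 0.41. With all measured members and cyclic loess the proteases were within the central 95%, at percentile 63.6. Interferon-stimulated genes (percentile 1.73, 10 of 27 lower and 0 higher, 2 lower and 2 higher after cyclic loess) and general macrophage genes (percentile 1.29) were low, with Ifit2 at −1.91 and the transcription factor Maf at −2.45. By the median over probe sets the interferon list was within the central 95%, at percentile 6.74.

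Both genotypes shared part of the IL-4 response. At 2-fold or more, 68 genes were higher in both, where independent lists would share 12.5, and 112 were lower in both, where they would share 28.2. After cyclic loess the shared genes were 96 higher and 72 lower, where independent lists would share 16.4 and 8.55. Of the 155 genes higher in wild type, 131 had the same sign on the arrays labelled Dap12-KO, and 154 of the 160 lower ones did. The median of all genes was −0.40 on those arrays as deposited, which by itself favours shared falls. After cyclic loess 148 of 165 higher and 127 of 141 lower genes had the same sign. Their median sizes on those arrays depended on the scaling: 0.87 against 1.44 in wild type for the higher genes and −1.45 against −1.22 for the lower ones as deposited, and 1.23 against 1.45 and −1.04 against −1.25 after cyclic loess. Ddx4, from below the floor, Edn1, Gatm, Cish, Plekhf1 and Ccl7 were among the genes higher in both, with 4.11, 3.75, 2.65, 3.49, 2.61 and 3.51 on the arrays labelled Dap12-KO. Fpr2, Cd24a, Sema4d and Fabp7 were among those lower in both, with −2.32, −3.14, −3.35 and −2.85. Only 1 of the 3 Sema4d probe sets went that way on the arrays labelled Dap12-KO. Across genes the IL-4 differences of both genotypes correlated at r = 0.342 (rho = 0.252), where genes are not independent replicates.

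**Figure D2:**
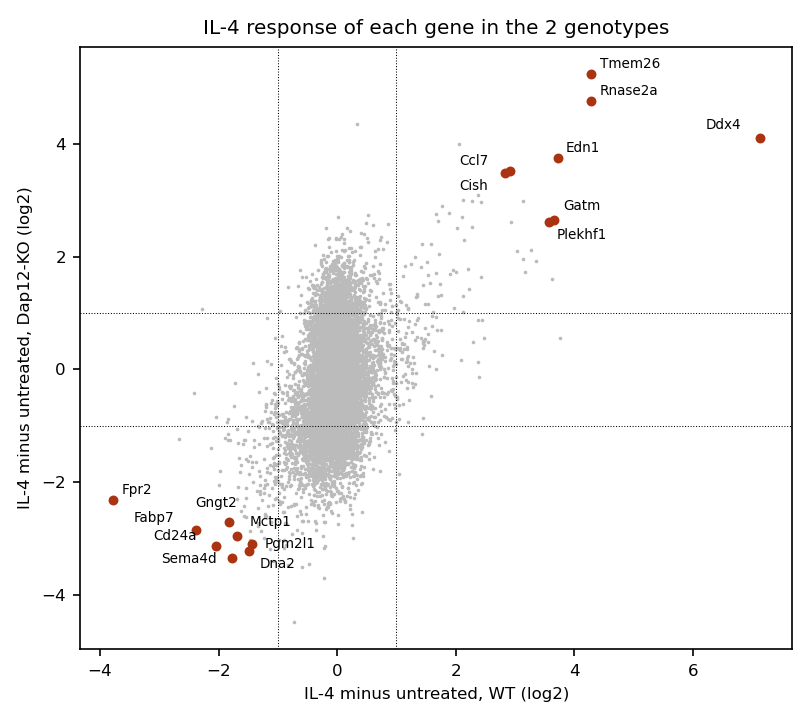
IL-4 response of each of 12767 genes, as log2 difference between IL-4 and untreated arrays, in wild type (x axis) and on the arrays labelled Dap12-KO (y axis). Red points are the 8 genes highest and the 8 lowest by the mean of both responses, among genes at 2-fold in the same direction in both, from Ddx4 at 7.13 and 4.11 to Fpr2 at −3.78 and −2.32, and dotted lines mark 2-fold.

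The 2 genotypes served as the replicates of IL-4 in a limma fit with genotype as a block, which left 1 residual degree of freedom. Its p-values measure only the spread between these 4 arrays, which may be technical. With limma, 69 genes rose and 141 fell with IL-4 at an adjusted p under 0.05, and 1246 genes had an unadjusted p under 0.05. Ddx4 rose by 5.62 (adjusted p = 3.48e-36, limma), Rnase2a by 4.52, Cish by 3.15, Cdh1 by 3.03, Arg1 by 2.64, Itgb3 by 2.41 and Ocstamp by 2.33. Fpr2 fell by 3.05 (adjusted p = 5.64e-10, limma). Cd24a (−2.59), Sirpb1a (−2.11), the receptor Tlr2 (−1.89) and Clec5a (−1.48) fell as well. Among the fixed lists, 15 of 31 alternative activation genes rose, or 20 adjusted over the list alone. Of 16 IL-4 receptor pathway genes 3 rose, and 4 passed adjusted over the list alone, of which 3 rose. In the fusion list 4 of 24 rose by either adjustment, and 3 of 27 interferon-stimulated genes fell, namely Oas3, Ifit2 and Ifit1, or 10 adjusted over the list alone. The fit's prior degrees of freedom, the weight given to the spread pooled over genes, were infinite. Every gene therefore received the same standard error, 0.42, so these calls follow the size of the difference alone. The p-values do not reflect how alike a gene's own responses were in both genotypes, which for Ddx4 were 7.13 and 4.11. The smallest called difference was 1.41. After cyclic loess the same limma fit called 0 genes, with 814 at an unadjusted p under 0.05 and a smallest adjusted p of 0.195.

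**Figure D3:**
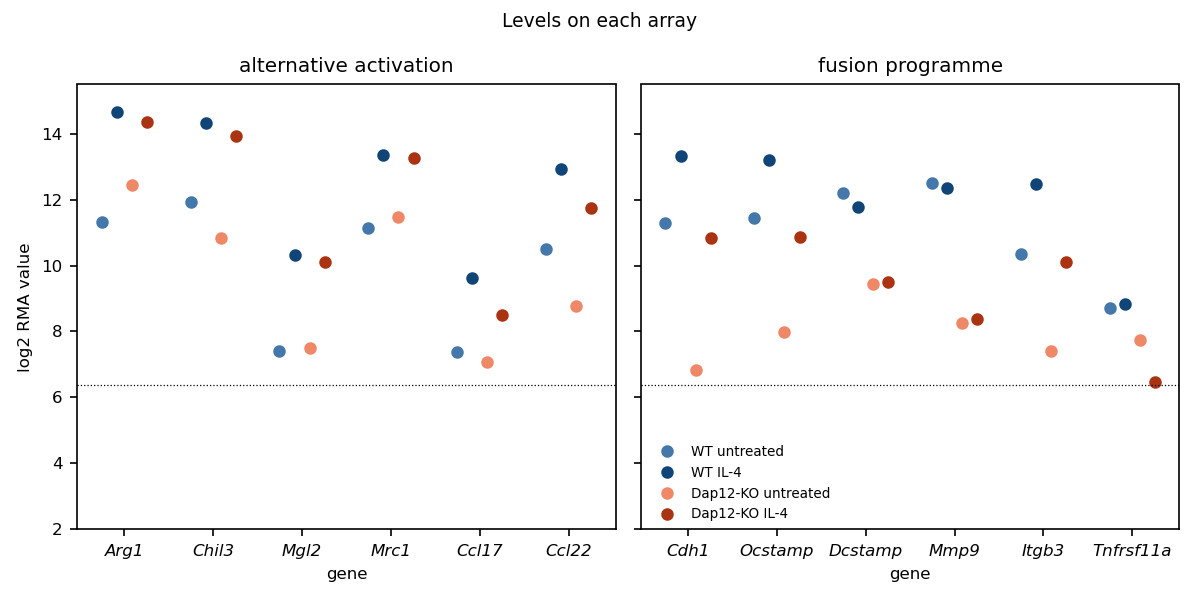
Levels of 6 alternative activation genes (left) and 6 fusion programme genes (right) on each of the 4 arrays, in log2 RMA units, with the level floor of 6.39 as a dotted line. The IL-4 arrays lie above the untreated arrays of the same genotype for all 6 genes on the left, and Mmp9 reads 12.52 and 12.37 in wild type against 8.27 and 8.37 on the arrays labelled Dap12-KO.

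Without treatment, the array labelled Dap12-KO held less transcript of fusion, matrix protease and inflammatory genes than the wild type array, and more of genes marking resident cavity macrophages. The gelatinase Mmp9 was 19.0-fold lower, Cdh1 21.6-fold and Itgb3 7.83-fold, and Ocstamp differed by −3.46. The protease inhibitor Timp1 differed by −3.37, the chemokine Cxcl3 by −3.51, and the DAP12 partner receptor Clec5a by −2.29. Mid1 (−6.24), G530011O06Rik (−4.49), Tmem178 (−4.25), Pcdh7 (−4.17) and Cracdl (−3.90) were also among the lowest, Mid1 in only 1 of its 3 probe sets. Mid1, Pcdh7, and Ptgs2 and Socs2 named below, lay below the level floor on this array, and Pdgfc and Nxpe4 on the wild type array, so the sizes of their differences rest on background readings. Higher on the array labelled Dap12-KO were the growth factors Pdgfc (3.72) and Tgfb2 (2.94), Nxpe4 (3.23), Dbp (3.06), Arhgap19 (3.04), the receptor Cd300lf (2.66), Iqgap2 (2.51) and the lysosomal sulfatase Sgsh (2.48). These directions rest on labels that the Tyrobp signal does not bear out.

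In all, 398 genes were higher and 435 lower on the untreated array labelled Dap12-KO. The fusion list had 7 of 24 members lower and 0 higher, with a median of −0.59. Matrix proteases had 6 of 12 lower and 1 higher, with Mmp19, Mmp13 and Serpinb2 at −1.92, −1.91 and −1.90 and a list median of −1.09. In the inflammatory list 9 of 21 were lower and 0 higher, among them Ptgs2 (−2.23), Ccl4 (−1.92) and Ccl3 (−1.66). Alternative activation genes had 12 of 31 lower and 2 higher, the latter being Arg1 (1.13) and the lipoxygenase Alox15 (1.39). Stress and immediate early genes had 7 of 29 lower and 0 higher, with Mt2 at −2.02 and the heat shock protein Hsph1 at −1.71. All 5 of these medians lay below all random lists. The lists are not fully separate, as Cdh1 stands in the fusion and alternative activation lists and Ccl2 in the fusion and inflammatory lists. Interferon-stimulated genes were also low for their level, at percentile 0.66, with 2 of 27 at 2-fold.

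Other lists were high on the untreated array labelled Dap12-KO. Of 15 resident cavity macrophage markers, 7 were higher and 0 lower, including Ltbp1 (1.78), F5 (1.33) and Prg4 (1.21), and their median of 0.84 exceeded all random lists. General macrophage genes had a median of 0.43, likewise above all random lists, led by Maf (2.19) and Mertk (1.97). Lysosomal genes (median 0.19, percentile 99.97, 0 of 28 at 2-fold) and fatty acid oxidation genes (0.30, percentile 99.93, 3 of 18 higher, with Fabp4 at 1.76 and Cpt1a at 1.43) were high too. The IL-4 receptor pathway list was at percentile 98.2 with a median of 0.23 but a mean of −0.03, with Socs2 at −2.29 and Irs2 at 1.19, and was at 97.4, inside the limits, by the median over probe sets. B cell markers were higher on the same array, with 4 of 13 higher and a percentile of 99.8, among them Bank1 (1.45) and Ighm (1.24). Mast cell markers went both ways, with Cma1 at 1.34 and Gata2 at −1.56. Their percentile was 99.7 over 5 genes, but 54.2 with all 11 measured members and 96.7 by the median over probe sets. Mesothelial and fibroblast markers (percentile 3.38), neutrophil (40.6), eosinophil (74.7), T and NK cell (20.2) and dendritic cell markers (10.1) lay within the central 95%, as did genes of DAP12 and its partners (17.6), MHC class II (87.8), cell division (85.4), cholesterol synthesis (9.76), LXR targets (80.9), glycolysis and hypoxia (65.2) and integrins (4.97). With all measured members, mesothelial and fibroblast markers were low, at percentile 0.17 over 20 genes, and T and NK cell markers were at the lower limit over 18.

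With IL-4, lower levels of fusion genes on the array labelled Dap12-KO remained in both scalings. Mmp9 differed by −4.01 (−3.30 after cyclic loess), Cdh1 by −2.48 (−1.79), the RANK receptor Tnfrsf11a by −2.39 (−1.85), Itgb3 by −2.37 (−1.65) and Ocstamp by −2.33 (−1.66). Mid1 (−7.27), G530011O06Rik (−5.75), the Notch ligand Jag1 (−4.09), the ERK phosphatase Dusp6 (−4.00), Tmem178 (−3.68), Pcdh7 (−3.56) and S1pr3 (−3.37) were lower too. Jag1 and Dusp6 were at −3.38 and −3.31 after cyclic loess. Mid1, Jag1, Dusp6, Pcdh7 and S1pr3 lay below the level floor on the array labelled Dap12-KO, so the sizes of their differences rest on background readings. Higher were Klk1b5 (4.16), the RNA editing enzyme Adarb1 (3.99), Cavin2 (3.69), Lce1d (3.68), Adam6b (3.60), Igha (3.49) and Pik3cd (3.32). Of these, Klk1b5, Cavin2, Lce1d, Adam6b and Igha were below the level floor on both wild type arrays, and Pik3cd was higher in 1 of its 6 probe sets. Of 31 alternative activation genes, 6 were lower, among them Flt1 (−2.96), Cdh1 and Ccl22 (−1.18), 2 were higher, Alox15 (1.28) and Rnase2a (1.15), and 23 were neither, such as Arg1 (−0.29, or 0.20 after cyclic loess) and Chil3 (−0.40, or 0.13). After cyclic loess 2 were lower and 5 higher.

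As deposited, 1387 genes were higher and 2245 lower on the IL-4 array labelled Dap12-KO than on the wild type IL-4 array, a split that became 1572 and 686 after cyclic loess, 1805 and 1002 after quantile normalization and 1056 and 3079 after median centring. The fusion list had 10 of 24 lower and 0 higher (percentile 0.83), and 6 of 24 lower after cyclic loess. Matrix proteases had 6 of 12 lower (percentile 0.02), with Mmp19 at −2.33 and Mmp13 at −1.11, and 1 of 12 after cyclic loess, while Serpinb2 was at 0.20, or 0.83 after cyclic loess. General macrophage genes (percentile 99.98), lysosomal genes (99.99), fatty acid oxidation genes (99.91) and resident cavity macrophage markers (99.58) stayed high for their level. Their medians as deposited were −0.21, −0.25, −0.21 and 0.06. In the same order 0, 0, 1 and 2 genes were higher and 2, 0, 0 and 0 lower at 2-fold. The alternative activation list was at percentile 99.97, although its median was −0.24 as deposited and 0.29 after cyclic loess. B cell markers were at percentile 96.4 and mast cell markers at 78.9. Inflammatory cytokines (percentile 79.1) and interferon-stimulated genes (94.5) lay within the central 95%.

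**Figure D4:**
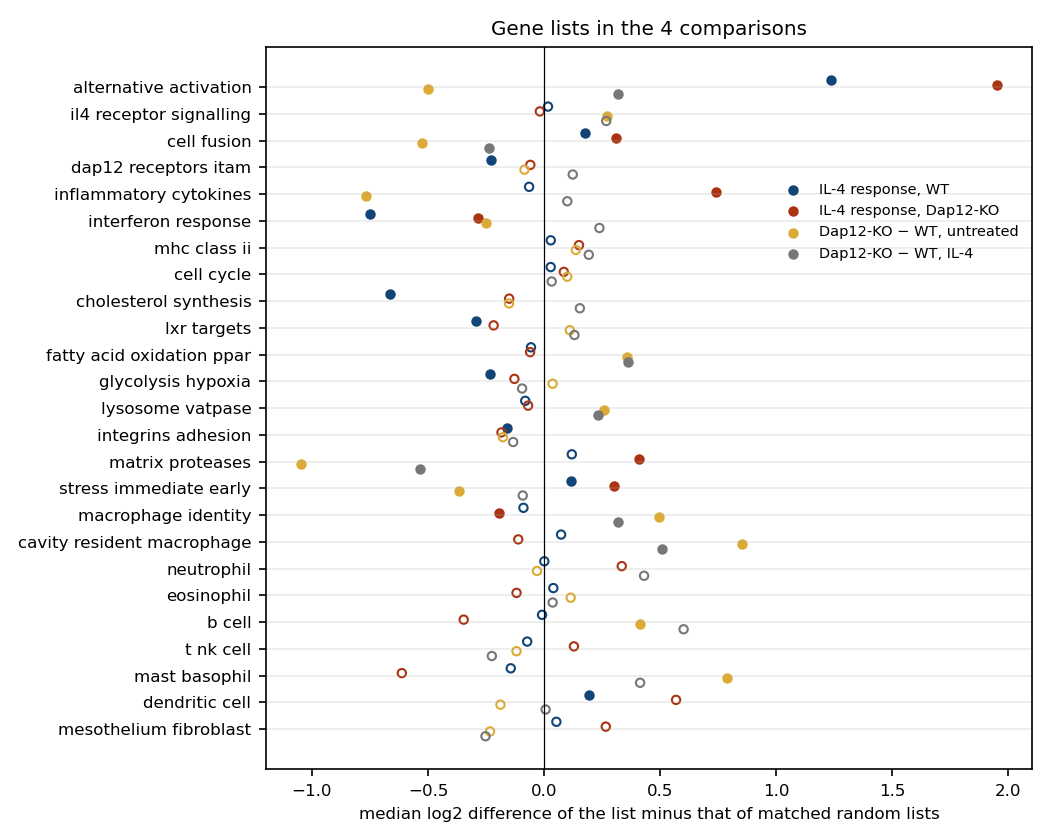
Median log2 difference of each gene list minus that of level-matched random lists (x axis) in the IL-4 comparison of each genotype and the genotype comparison of each treatment. Filled points lie outside the central 95% of 10000 random lists, as alternative activation does in all 4 comparisons and matrix proteases in all but IL-4 in wild type. Values are as deposited, and after cyclic loess every filled point stayed outside.

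Genotype differences resembled each other in both treatments. Across genes they correlated at r = 0.479 (rho = 0.509), and 48 genes were higher and 329 lower on the arrays labelled Dap12-KO in both treatments, where independent lists would share 43.2 and 76.5. After cyclic loess these were 145 and 144, where independent lists would share 58.7 and 20.2. After quantile normalization they were 103 and 159, against 57.9 and 28.2. Of the 398 genes higher untreated, 238 had the same sign with IL-4 as deposited, and 430 of the 435 lower ones did. After cyclic loess these were 386 of 465 and 347 of 366. At 2-fold, 24 genes went opposite ways as deposited and 9 after cyclic loess. Mid1, Mmp9, Cdh1, Tmem178, Pcdh7, Ocstamp, Itgb3, Vcam1 (−2.35 and −2.31) and Vegfa (−2.13 and −2.09) were lower in both treatments. Tgfb2 (2.94 and 1.77) and Alox15 (1.39 and 1.28) were higher in both.

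The IL-4 response itself differed between genotypes for some genes, a difference that 4 arrays leave without a test. The response on the arrays labelled Dap12-KO exceeded that in wild type by 4.02 for Ch25h, 3.34 for Vsig8, 2.70 for the deacetylase Hdac11, 2.69 for the homeobox gene Hoxa5, 2.58 for Baat and 2.47 for Serpina1b. It fell short for Nxpe4 (−3.75), Fli1 (−3.48), Gpr155 (−3.26), S1pr3 (−3.20), Ddx4 (−3.02) and Zfp467 (−3.01). All 12 stayed beyond 2-fold in the same direction after cyclic loess. Nxpe4, Fli1, Gpr155, Zfp467 and S1pr3 lay below the level floor on the IL-4 array labelled Dap12-KO, and Ddx4 on both untreated arrays and Serpina1b on all but that array did too. Ch25h read 6.42 on the untreated array labelled Dap12-KO, just above the floor, and differed by 0.96 between both IL-4 arrays. S1pr3 was at 9.70 in wild type with IL-4 and at 6.33 on the IL-4 array labelled Dap12-KO. Alternative activation genes had a median response difference of 0.35, above all random lists, with 5 of 31 higher and 2 lower. Inflammatory cytokines (0.36) and stress genes (−0.09) also exceeded all random lists, as did cholesterol synthesis genes (−0.12), and the last 2 medians turned positive after cyclic loess, to 0.33 and 0.49. Interferon-stimulated genes were at percentile 99.99 and the fusion list at 98.99, with medians of 0.06 and −0.30 as deposited. By the median over probe sets the fusion list (79.8) and cholesterol synthesis (96.7) lay within the central 95%. High percentiles here are partly built in for the alternative activation, inflammatory, stress, fusion and interferon lists. These lists were low on the single untreated array labelled Dap12-KO from which the response is measured. Over all genes, 1041 exceeded and 1893 fell short by 2-fold, against 1120 and 716 after cyclic loess, 1453 and 1003 after quantile normalization and 742 and 2614 after median centring.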

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

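The tests of hybridisation controls, of cell type lists with all members, of counts after cyclic loess, of RNA degradation, of swapped labels, of probe position, of the chromosome of Tyrobp and of Mid1 with Erdr1 were chosen only after the results they measure had been seen; the tests of cell type lists above the floor and of the neighbours of Tyrobp were written first. The test of the chromosome was added once the neighbours' result was known. The verdicts on the neighbours, other cell types, the hybridisation controls and Mid1 with Erdr1 were changed to undecided after their values had been seen. The first 2 had met the limits set in advance for arguing against those explanations, and the last 2 had first been read as fitting.

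IL-4 went with opposite moves of at least 2-fold in the 2 genotypes for 3 genes, a difference that was not tested. The hypoxia-induced gene Ndrg1 differed by 1.42 in wild type and by −1.14 on the arrays labelled Dap12-KO, or −0.47 there after cyclic loess. Rnf180 differed by 1.04 and −1.86, with 1 of its 2 probe sets going each way. Vsig8 differed by −2.28 and 1.07.

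The array labelled Dap12-KO with IL-4 had 3275 genes at 2-fold against its untreated partner, where wild type had 315. RNA degradation is argued against, since the gap between 3' and 5' probe sets of Gapdh and Actb grew by at most 0.0888, and so is a level trend that cyclic loess removes as the whole cause, since 1993 genes stayed at 2-fold against 306 in wild type, a ratio of 6.51. A response specific to this genotype stays open, untested, and so do other cells: 0 of 8 cell type marker lists lay above the central 95% of random lists in both scalings, but with all 13 measured members the neutrophil list was at percentile 98.1, or 97.2 after cyclic loess, although S100a8 differed by −1.65. A distortion of the array's signal stays open too: controls added at hybridisation shifted by a median of −0.42 where probe sets of the same level shifted by −0.66, against 0.24 for the controls in wild type, and poly-A controls shifted by −0.93 against −0.38 in wild type. Yet all 18 hybridisation controls also read lower between both untreated arrays, by −0.25, where probe sets of the same level shifted by −0.05.

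Tyrobp was bright on both arrays labelled Dap12-KO. A swap among the 4 arrays is argued against as the source of this signal, since it would need an array without signal under a wild type label, and the lowest value of the 4, 13.27, lies far above the floor of 6.39. Whether labels were swapped is not settled by this, because a probe set outside the deleted part would be bright on every array. Such a probe set, a transcript left after targeting and samples that are not knockouts could each give such a signal. The probe set's place relative to the deletion is known for 0 probe sets, so these cannot be told apart.

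Genotype differences at 2-fold in both treatments numbered 377. Position on the chromosome of Tyrobp is argued against as the whole cause, because 6.56% of the 366 placed genes (24) lie there, where 7.95% of all genes do. Carried genes may also act on genes of other chromosomes, which this share cannot show, so that stays open. Among the 50 measured genes on each side of Tyrobp in GRCm38.p6 the share was 1.33 times that of other genes (4 of 100 against 362 of 12057, two-sided Fisher's exact p = 0.547), and the exact 95% interval of the neighbours' share, 0.367 to 3.31 times, leaves a contribution there open. A difference of mouse strain may contribute, as Mid1 and Erdr1, which lie at the end of the X chromosome, both differed by at least 2.28 log2 units in both treatments, but they were picked because they differed and decide nothing. Loss of DAP12 signalling stays open as the biological explanation, and was not tested apart from these. The mix of cells was not weighed for these differences. Resident cavity macrophage markers were at percentile 100 untreated and 99.58 with IL-4, and B cell markers at 99.8 and 96.4.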

How the results depend on the processing

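Quantile normalization, all list members with cyclic loess, and cyclic loess for the genes shared by both treatments, were chosen only after results had been seen. Median centring and the median over probe sets moved no count over all genes by over 1.5 times, and the correlation of genotype differences stayed between 0.450 and 0.541 under all its alternatives. With a 3-fold threshold the counts were 92 and 811 for IL-4 in wild type and Dap12-KO, 229 and 986 for genotype untreated and with IL-4, and 662 for the response difference, as the threshold implies. Counting every probe set gave 552, 6908, 1673, 8430 and 6590 in the same order, from more features. A floor at the 75th percentile gave 2120 for IL-4 in Dap12-KO, 2123 for genotype with IL-4 and 1714 for the response difference, with fewer genes tested. It raised the IL-4 correlation to r = 0.479. Higher genes went from 1026, 1387 and 1041 to 329, 314 and 275, in the same order. Lower genes went from 2249, 2245 and 1893 to 1791, 1809 and 1439. Most higher genes of these comparisons were thus dim ones below that floor on every array. After cyclic loess, with the main floor, the totals of these comparisons were 1993, 2258 and 1836, and the cause of the remainder was not tested.

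The limma calls for IL-4 were the least stable. They went from 210 to 0 with cyclic loess (814 at an unadjusted p under 0.05), 0 with quantile normalization (598) and 0 with no level floor (962), to 118 with an intensity trend, of which 116 were shared, and to 7 without the genotype term. With a floor at the 75th percentile 190 of 212 calls were shared, and with the median over probe sets 135 of 189. A limma genotype term called 454 genes, but 0 after cyclic loess (1996 at an unadjusted p under 0.05) and 0 after quantile normalization (1350). The prior degrees of freedom changed with these calls. For both terms they were infinite with the main settings, 3.48 after cyclic loess and 2.82 after quantile normalization. For IL-4 with no level floor they were 5.32. Fits with 0 calls thus leaned less on the pooled spread. In fits with a genotype term, the spread comes from each gene's response difference between genotypes. The median of that difference was −0.36 with the main settings and −0.55 with the floor at the 75th percentile. It was −0.51 with median centring and −0.31 with the median over probe sets, and in all of these the prior was infinite. With no level floor, cyclic loess and quantile normalization it was −0.05, 0.07 and 0.04. Calls were thus made only where the median gene was shifted. Why the prior changed was not tested. Leaving out any array leaves no residual degree of freedom, so no such fit was run. Some list medians changed sign with cyclic loess, but no list passed from high to low for its level, and of 125 list percentiles 4 moved past the limits and 0 back inside with cyclic loess, 3 and 0 with quantile normalization, 5 and 2 with all list members, 5 and 5 with the median over probe sets, and 12 and 3 with all list members and cyclic loess. The last 3 were proteases for IL-4 in Dap12-KO, mast cell markers for genotype untreated (percentile 43.5) and dendritic cell markers for IL-4 in wild type (49.8). Genes below the floor, where signal nears background, limit what lower levels can show.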

Other observations

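The tests of the ERK, FOXO and clock lists were written before the lists' values were seen, but the lists were drawn up after single genes had drawn attention, and those genes were left out of them. The verdict on the clock list was changed after its value had been seen: the value met the limit set in advance for arguing against a different clock phase, and it is now read as undecided.

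Genes known as outputs of the ERK pathway were low on the untreated array labelled Dap12-KO, with 9 of 16 at least 2-fold lower, 0 higher and a median of −1.34. Fosl1 differed by −2.59, Dusp4 by −2.34, Maff by −2.14, Dusp5 by −2.06 and Spred1 by −1.42. With IL-4 the median was −0.95, and −0.31 after cyclic loess with 3 of 16 lower and 2 higher. The highest percentile of the list over both treatments and both scalings was 0.44, in line with a hypothesis of lower ERK output on the arrays labelled Dap12-KO. Plaur, Myc, Egr1 and Ier3 of this list also stand in fixed lists that were low on the untreated array labelled Dap12-KO. The evidence is thus not fully separate, and the Tyrobp signal leaves the genotype itself unchecked.

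Fbxo32 (2.45) and Cxcr4 were high on the untreated array labelled Dap12-KO. Other known FOXO targets had 8 of 17 higher and 0 lower there, with a median of 0.94, led by Ccng2 (1.89), Klhl24 (1.74) and Tsc22d3 (1.65). Irs2 (1.19), among the higher ones, also stands in the fixed IL-4 receptor list. The list's percentile was 100 in both scalings, in line with a hypothesis of higher FOXO target expression in these untreated cells. Between both IL-4 arrays the list lay within the central 95%, at percentile 78.0 as deposited and 83.7 after cyclic loess. From untreated to IL-4 on the arrays labelled Dap12-KO 13 of 17 were lower, or 7 of 17 after cyclic loess, a fall that is partly built in because it starts from the same single array on which the list was high.

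The high Dbp level of the untreated array labelled Dap12-KO may come from a different clock phase at harvest, and the test leaves this open. The list of other clock genes was at percentile 70.8, and 0 of Nr1d1, Per3 and Tef reached 2-fold, with Tef just short at 0.995 and past it after cyclic loess, at 1.10. A list median was a poor test, because clock genes peak at different times and the members went both ways: Nr1d2 differed by 1.28 and Per3 by 0.60, Per2 by −0.60, Arntl by −0.34 and Npas2 by 0.23.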
